A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

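RNA was measured in 4 libraries of strain BY4742, 2 from cultures given 5 mM TUDCA for 2 h and 2 from control cultures. Groups follow the sample labels. Libraries were stranded, poly(A)-selected and made from RNA with an integrity number above 8, per the labels. The deposited counts are raw counts per gene, 1 column per library. Per the submitters' processing notes, reads were aligned with STAR 2.5.4b to build R64 and counted with featureCounts 1.6.0, and DESeq2 1.26.0 was used. The deposited signal values are these counts divided by 1 size factor per library (0.899, 1.15, 0.930 and 1.05 for Ctrl replicates 1 and 2 and TUDCA replicates 1 and 2), checked from the constant ratio of the 2 tables. Multimapping rule, annotation release and strand setting: not given in the sources used here.

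Strand handling was checked from the counts. Of 112 features covered over their whole length by features on the opposite strand, 111 (99.1%) had 0 counts in all libraries, against 51 of 5726 (0.891%) covered by no other feature and 24 of 926 (2.59%) covered in part. Counting therefore ignored strand, and reads in overlaps were not assigned to a gene. HYP2 and DID2 are listed at 0 for this reason. Another feature overlapped 7 of 54 named genes and 79 of 812 list members. The identical genes TEF1 and TEF2 both had counts.

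The count table held 7127 features, of which 6047 matched the reference gene table by locus tag and 1080 did not. Feature coordinates lay within the R64 chromosome lengths. Libraries held 74080860 to 97133389 assigned counts, and counting error was small beside the spread between libraries (chi-square per degree of freedom 39.7 between the TUDCA libraries and 174 between the Ctrl libraries). A count of 0 allows up to 3 counts in a library, and such limits cover counting error only. The 20 most abundant genes held 12.3% to 13.4% of the counts, and nuclear ribosomal RNA loci 0.000171% to 0.000236%. The ribosomal RNA share may understate its content, since reads in overlaps were not assigned and the multimapping rule is not given. Mitochondrial ribosomal RNA is not in that share: its 21S gene was at 64.8 CPM in Ctrl and 47.1 CPM in TUDCA.

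Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr, at a minimum count of 10, kept 6420 genes (5878 protein coding) and left out 707. TMM factors scaled the libraries, and group differences were tested with edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.00695 (biological coefficient of variation 8.34%), with 2 residual and 5.71 prior degrees of freedom. CPM values (counts scaled by library total) are also scaled by TMM factors, except the limit for 0 counts in the strain check. On simulated data with 2 libraries per group and 6405 genes, the same test called 83.6% of 67 genes changed 1.5-fold, 95.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 17 of 6205 unchanged genes. Simulated genes were independent, and no library was set apart from the others. Many more genes were changed in the simulation than were called in the data, which eases the Benjamini-Hochberg threshold. The simulated rates may therefore overstate those in the data.

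A total of 42 gene lists was written before the data were examined, and the 41 with at least 3 measured members, counting out the strain check, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the lists. They covered ER folding, ER-associated degradation, ER translocation, cell wall integrity, general stress, heat shock, oxidative stress, osmotic stress and weak acid genes. Ribosomal protein, ribosome biogenesis, proteasome, autophagy, histone, G1/S, G2/M, daughter separation and meiosis genes were covered too. Metabolic lists were ergosterol, sterol uptake, phospholipid, fatty acid, sphingolipid, respiratory chain, tricarboxylic acid cycle, peroxisome, glycolysis, hexose transport, amino acid, sulfur, nitrogen, purine, iron, phosphate and zinc genes. The others were drug resistance, vacuolar ABC transporter, pheromone, α-specific, a-specific and mitochondrially encoded genes. With an estimated correlation, camera's test has only the 2 residual degrees of freedom, so a list can fail it whatever the correlation of its genes. Members were also adjusted over their list alone, which does not control error across the 41 lists. Intervals of list medians are order-statistic 95% intervals over genes, or the full range for small lists.

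Genes were named by a rule written before the data were examined. It took up to 15 called genes per direction with a mean of at least 10 CPM and non-overlapping groups, the 5 smallest adjusted p per direction, up to 4 called members per list or else the member with the smallest p, and a fixed set (HAC1, KAR2, ERO1, INO1, SLT2, YBT1, PDR5, JLP1, HSP12 and the markers). With fewer than 10 calls, the 10 smallest p were named as well. Other genes, such as those past the adjustment over their list alone, GDH1, PDR15 and PDR3, were named after their values were seen.

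The alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, and limma on log2 of the deposited signal with a pseudocount of 1. Others were no low-count filter, a mean count of at least 100, robust dispersion, a replicate block, leaving out each library, an adjusted p of 0.01, a log2 fold change of at least 1, and for lists fry and ranks. Thinned counts, a fit without ribosomal protein genes, and removal of a loess trend (span 0.5) on gene length and GC were added after the data were examined. With 1 library left out of a group, the lone library was assumed to vary like those of the other group.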

Results

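The transcriptome of budding yeast was measured after treatment with tauroursodeoxycholic acid (TUDCA), a taurine-conjugated bile acid used as a chemical chaperone that eases stress in the endoplasmic reticulum (ER). The strain was BY4742, a haploid laboratory strain of mating type α. Cultures growing exponentially in rich glucose medium received 5 mM TUDCA for 2 h, or no TUDCA (Ctrl), and poly(A)-selected RNA was sequenced. There were 2 libraries per group, so every mean below is over n = 2 and every error is an SD unless another is named. Counts assigned to genes totalled 74080860 in Ctrl replicate 1 and 97133389 in Ctrl replicate 2. They totalled 74963319 in TUDCA replicate 1 and 85380303 in TUDCA replicate 2. Protein-coding genes held between 99.6% and 99.7% of the counts in every library. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

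The counts matched the strain's auxotrophic markers. LEU2 and URA3 had 0 counts in all 4 libraries, which allows up to 3 counts per library, or 0.0405 CPM (counts scaled by library total, here without TMM factors) in the smallest library; this floor covers counting error only. LYS2 had at most 2 counts in a library. HIS3, whose allele in this strain is a partial deletion, kept between 11172 and 17246 counts. Its level, scaled by TMM factors like all CPM values below, was 177 ± 7.84 CPM in Ctrl and 142 ± 6.10 CPM in TUDCA (log2 fold change -0.32, edgeR adjusted p = 0.492). These checks concern the strain and not the treatment.

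Ctrl replicate 2 stood apart from the other 3 libraries. Across genes, the log2 expression of the other libraries correlated at r = 0.998 in each pair, and that of Ctrl replicate 2 with each of them at 0.992 to 0.995. The SD of log2 ratios across 5969 genes was 0.24 to 0.30 in pairs with Ctrl replicate 2 and 0.12 to 0.15 in pairs without it. Genes are not independent replicates, so these values describe the libraries only. Cytosolic ribosomal protein genes took 13.3% of the counts in Ctrl replicate 2 and 9.75% to 10.4% in the other libraries. No libraries were copies of each other, since the chi-square per degree of freedom between the 2 TUDCA libraries was 39.7 and between the 2 Ctrl libraries 174.

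The comparison of TUDCA with Ctrl asked how the yeast transcriptome responds to the bile acid. The drug efflux pump gene PDR5 rose from 324 ± 4.67 to 744 ± 56.3 CPM, a 2.30-fold increase. GRE2, which encodes a stress-induced methylglyoxal reductase, rose 1.6-fold. The genes that fell were AGA1 and SAG1, which encode parts of the mating agglutinins, FUS1, needed for mating-cell fusion, and ANB1, the hypoxic form of translation factor eIF5A. Each of these 4 was between 1.86-fold and 2.25-fold higher in Ctrl. No other gene passed the test.

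For PDR5 (YOR153W, chromosome XV, 619840 to 624375, build R64) the log2 fold change was 1.20 (SE 0.10) with an adjusted p of 0.00465 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 6420 genes. GRE2 (YOL151W, chromosome XV, 43694 to 44722) went from 109 ± 4.68 to 175 ± 1.03 CPM, with a log2 fold change of 0.68 (SE 0.080, edgeR adjusted p = 0.0372). A feature on the opposite strand covered 24.3% of GRE2, and reads from that stretch were not counted. AGA1 (YNR044W, chromosome XIV, 703699 to 705876) went from 103 ± 1.80 to 53.2 ± 0.764 CPM, a log2 fold change of -0.96 (SE 0.074, edgeR adjusted p = 0.00465). SAG1 (YJR004C, chromosome X, 442909 to 444861) went from 175 ± 8.46 to 87.4 ± 2.61 CPM, a log2 fold change of -1.0 (SE 0.082, edgeR adjusted p = 0.00465). FUS1 (YCL027W, chromosome III, 71803 to 73341) went from 37.2 ± 1.19 to 20.1 ± 1.16 CPM, a log2 fold change of -0.89 (SE 0.092, edgeR adjusted p = 0.0181). ANB1 (YJR047C, chromosome X, 524908 to 525381) went from 93.9 ± 9.77 to 41.7 ± 2.20 CPM, a log2 fold change of -1.17 (SE 0.096, edgeR adjusted p = 0.00465). ANB1 has a close paralog, HYP2, which is listed at 0 counts in every library because of the way overlapping genes were counted, so reads shared between the copies could not be assessed. For each of the 6 genes, both TUDCA libraries lay on the same side of both Ctrl libraries. GRE2 lost its call when TUDCA replicate 1 was left out (edgeR adjusted p = 0.0569) and under upper-quartile scaling (edgeR adjusted p = 0.0600).

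**Figure D1:**
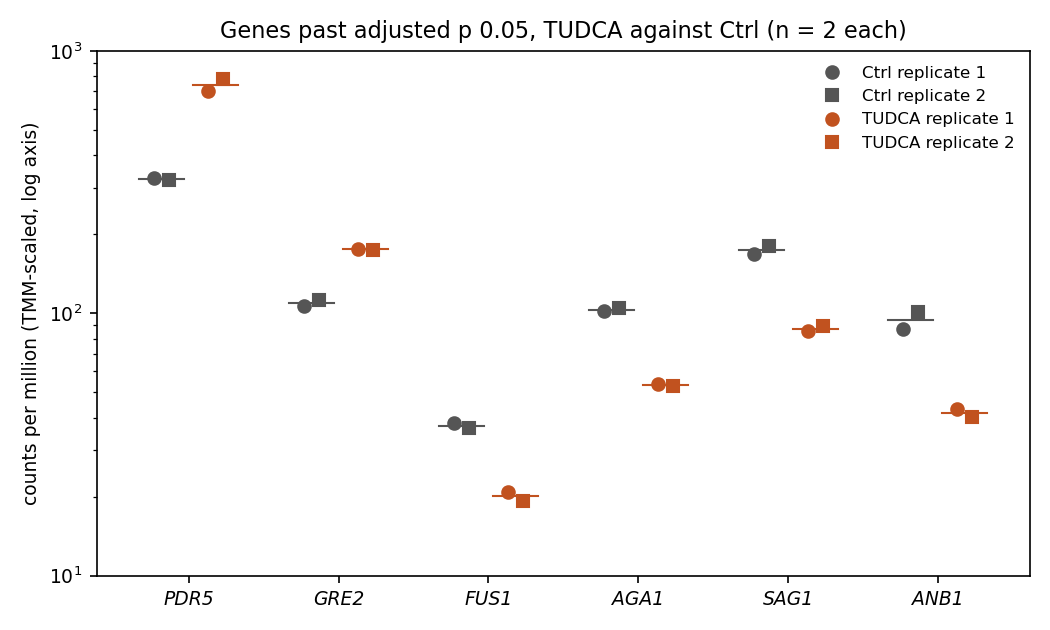
CPM values, scaled by TMM factors and on a log axis, of the 6 genes past an adjusted p of 0.05 in each library, with points for libraries (grey Ctrl, orange TUDCA, circles replicate 1, squares replicate 2) and lines for group means. PDR5 lies at 324 CPM in Ctrl and 744 CPM in TUDCA, and ANB1 at 93.9 and 41.7 CPM.

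The 6 calls, 2 higher and 4 lower, came from 534 genes with an unadjusted p under 0.05. limma-voom, and limma on the deposited normalized values, called the same numbers, and each kept all 6 genes. DESeq2 called 30 higher and 29 lower, again with all 6 among them. Upper-quartile scaling gave 1 higher and 4 lower. The count depended on which library was left out. It was 1139 higher and 871 lower without Ctrl replicate 1, 24 and 19 without Ctrl replicate 2, 2 and 5 without TUDCA replicate 1, and 12 and 10 without TUDCA replicate 2.

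The next 4 genes by p did not pass edgeR's test. YML131W, a gene related to medium-chain reductases, had a log2 fold change of 0.77 (adjusted p = 0.0619). The cell wall mannoprotein gene TIR1 had -1.44 (adjusted p = 0.0796), with 168 ± 56.0 CPM in Ctrl against 62.1 ± 4.78 CPM in TUDCA. ICS2 had -0.60 (adjusted p = 0.0796) and IZH4, which encodes a membrane protein linked to zinc, -0.69 (adjusted p = 0.0873).

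Genes of ER protein folding and the unfolded protein response stayed close to their control level. KAR2, the ER Hsp70 chaperone and a standard target of the response, was at 726 ± 91.4 CPM in Ctrl and 737 ± 4.71 CPM in TUDCA, a log2 fold change of 0.022 with a 95% interval from -0.24 to 0.29. HAC1, the transcription factor of the response, had a log2 fold change of -0.031 (-0.26 to 0.19), and these gene-level counts do not measure the splicing of its mRNA. The thiol oxidase gene ERO1 had -0.075 (-0.26 to 0.11) and the sensor gene IRE1 0.13 (-0.040 to 0.30). The sign for KAR2 flipped under upper-quartile scaling (-0.019), with length and GC offsets (-0.051) and without Ctrl replicate 2 (-0.099), and that for HAC1 under library-size scaling (0.014) and without Ctrl replicate 2 (0.055).

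Among the 16 measured members of that list, edgeR, DESeq2, limma-voom and limma on the deposited values each called 0, and 0 had an unadjusted p under 0.05. The list's median log2 fold change was -0.026, with adjusted p = 0.868 in camera, a test of whether a list moved relative to the other genes. For 16 genes of ER-associated degradation the median was 0.028 (camera adjusted p = 0.392), and for 20 genes of ER translocation and glycosylation -0.023 (camera adjusted p = 0.644). Neither list had a member called by any of those tools or with an unadjusted p under 0.05. UBX2, at 0.24, and ALG7, at 0.17, had the smallest p in them. In Ctrl replicate 2 the ER folding list lay 0.032 above Ctrl replicate 1.

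**Figure D2:**
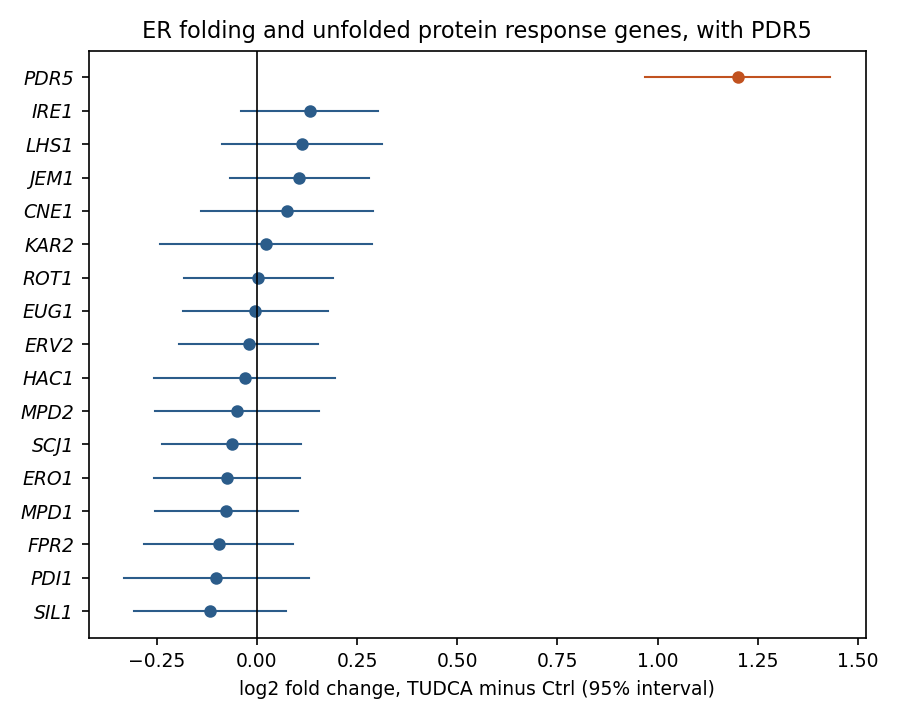
Log2 fold changes (TUDCA minus Ctrl) with 95% intervals for the 16 genes of the ER folding and unfolded protein response list, with PDR5 as a called gene for scale. All 16 intervals include 0, while that of PDR5 runs from 0.97 to 1.43.

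Targets of the drug resistance regulators Pdr1 and Pdr3 were higher in TUDCA as a list with camera's preset correlation (median 0.21, adjusted p = 4.0e-08), but not with an estimated one (adjusted p = 0.499 with an estimated correlation). The estimate was -0.0014, below the preset 0.01, so that loss does not come from correlation between the genes. Of 15 measured members, 1 rose (PDR5) and 14 did not pass. Adjusted over the list alone, which leaves error across lists uncontrolled, 5 rose. Besides PDR5, these were the ABC transporter genes YOR1 (log2 fold change 0.49) and SNQ2 (0.34), the polyamine transporter gene TPO1 (0.33) and RSB1 (0.34), a membrane protein of sphingoid base release. DESeq2 called 3 members. PDR15, the closest paralog of PDR5, had 0.21 (edgeR adjusted p = 0.544), and PDR3 itself 0.061. The list's median was 0.12 without Ctrl replicate 2, a library that lay 0.072 below Ctrl replicate 1 for this list, and 0.072 once a trend on gene length and GC was removed. Of those 5, PDR5, YOR1 and TPO1 still passed without TUDCA replicate 1, and PDR5 and YOR1 without TUDCA replicate 2.

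The 5 vacuolar ABC transporter genes include the bile acid pump gene YBT1. All 5 members had both TUDCA libraries above both Ctrl libraries. For a gene, chance separates the groups 33.3% of the time, both directions counted together, and genes of a list are not independent. YBT1 had a log2 fold change of 0.13 (95% interval -0.066 to 0.32), which reversed to -0.0078 with length and GC offsets, and YCF1, a glutathione conjugate pump gene, 0.17 (-0.028 to 0.36). The tools edgeR, DESeq2 and limma called 0 members, and 0 had an unadjusted p under 0.05. The list's median was 0.17 (camera adjusted p = 0.0312, and adjusted p = 0.686 with an estimated correlation). The call was lost without Ctrl replicate 1 (camera adjusted p = 0.105) and without TUDCA replicate 2 (0.175), and Ctrl replicate 2 lay 0.089 below Ctrl replicate 1. The list also did not pass with the replicate block (camera adjusted p = 0.0556). With a trend on gene length and GC removed, the median was 0.029.

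Pheromone response genes were lower in TUDCA as a list with camera's preset correlation (median -0.26, adjusted p = 1.1e-16), but not with an estimated one (adjusted p = 0.462 with an estimated correlation). The estimate was -0.025, below the preset 0.01, so correlation between these genes does not account for that loss. The test with an estimated correlation has only 2 residual degrees of freedom. In the list of 17 pheromone response genes, 2 fell (AGA1 and FUS1) and 15 did not pass, and 8 fell when adjusted over the list alone. The others of those 8 were KAR4, a transcription factor of mating (-0.49), the MAP kinase gene FUS3 (-0.32), PRM1 (-0.46), SST2 (-0.30), PRM6 (-1.10) and FIG1 (-0.61). PRM6 had only 32 to 123 counts per library, and a feature on the opposite strand covered 22.9% of it. Both TUDCA libraries lay below both Ctrl libraries for 13 of the 17. DESeq2 called 4 members. Of the 8, AGA1, FUS1 and KAR4 still passed without TUDCA replicate 1, and these and PRM6 without TUDCA replicate 2. FIG1 was at -0.37 without Ctrl replicate 2, which lay 0.036 above Ctrl replicate 1 for this list.

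The 4 genes specific to α cells were likewise lower as a list with the preset correlation (median -0.66, camera adjusted p = 2.7e-15), but not otherwise (adjusted p = 0.530 with an estimated correlation). SAG1 fell over all genes and 3 did not pass, and adjusted over the list alone all 4 fell, namely SAG1, the α-factor genes MF(ALPHA)1 (-0.43) and MF(ALPHA)2 (-0.90), and the a-factor receptor gene STE3 (-0.31). MF(ALPHA)1 was the most abundant, at 1724 ± 258 CPM in Ctrl and 1278 ± 43.7 CPM in TUDCA. DESeq2 called 3 of the 4. Of the 4, SAG1 and MF(ALPHA)2 still passed without TUDCA replicate 1, and these and STE3 without TUDCA replicate 2. MF(ALPHA)1 was at -0.27 without Ctrl replicate 2. For this list Ctrl replicate 2 lay 0.23 above Ctrl replicate 1. Of 7 genes specific to a cells, which an α strain represses, edgeR, DESeq2 and limma called 0, and 0 had an unadjusted p under 0.05. Their median was -0.012 (camera adjusted p = 0.895). The a-factor gene MFA2 was at 2.05 ± 0.0335 CPM in Ctrl and 1.67 ± 0.0622 CPM in TUDCA.

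The list of sterol uptake and anaerobic cell wall genes was lower with camera's preset correlation (median -0.15, mean -0.31, adjusted p = 4.8e-08), but not with an estimated one (adjusted p = 0.530 with an estimated correlation). ANB1 fell among 14 measured members and 13 did not pass, while 5 fell when adjusted over the list alone. The others were TIR1 (-1.44), TIR3 (-0.40), DAN1 (-0.88), which encode cell wall mannoproteins, and the haem synthesis gene HEM13 (-0.28). DAN1 had only 92 to 238 counts per library. DESeq2 called 3. Of the 5, ANB1, TIR1 and DAN1 still passed without TUDCA replicate 1, and ANB1, TIR1 and TIR3 without TUDCA replicate 2. Ctrl replicate 2 lay 0.11 above Ctrl replicate 1. The median was -0.25 once a trend on gene length and GC was removed. Members of the list did not move together, since 5 of the 14 had fitted values above 0.

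Zinc and fatty acid genes were lower as lists only with camera's preset correlation (adjusted p = 0.676 for zinc and adjusted p = 0.834 for fatty acid genes with an estimated correlation). Of 10 targets of the zinc regulator Zap1, edgeR called 0, DESeq2 1 and limma 0, while 3 had an unadjusted p under 0.05. IZH1, at -0.65 (edgeR adjusted p = 0.258), was the 1 gene lower when adjusted over the list alone, and was at -0.41 without Ctrl replicate 2. That list's median was -0.17 (camera adjusted p = 0.00240 with the preset and adjusted p = 0.676 with an estimated correlation), and Ctrl replicate 2 lay 0.088 above Ctrl replicate 1. Of 12 fatty acid synthesis genes edgeR and limma called 0 and DESeq2 2, with 3 at an unadjusted p under 0.05. Adjusted over the list alone, 2 fell, the Δ9 desaturase gene OLE1 (-0.49, from 391 ± 41.4 to 278 ± 7.79 CPM) and the acyl-CoA synthetase gene FAA4 (-0.33). The median was -0.089 (camera adjusted p = 0.0290, and adjusted p = 0.834 with an estimated correlation). The fatty acid call was lost without Ctrl replicate 1 (camera adjusted p = 0.0594), without Ctrl replicate 2 (0.0807, median -0.0096) without TUDCA replicate 1 (0.244, median -0.053) and on ranks (0.0879). Without TUDCA replicate 2 the median was -0.14, as it was once a trend on gene length and GC was removed. Neither OLE1 nor FAA4 passed the adjustment over the list alone without TUDCA replicate 1 or without TUDCA replicate 2. Ctrl replicate 2 lay 0.081 above Ctrl replicate 1 for the fatty acid list.

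Cytosolic ribosomal protein genes had fitted values below 0 in TUDCA, to an extent that depended on Ctrl replicate 2. All 137 lay below 0, from -0.44 (RPL22B) to -0.099 (RPL10) with a median of -0.29, although edgeR and limma called 0 and DESeq2 1, and 20 had an unadjusted p under 0.05. RPS22B, at -0.43 (edgeR adjusted p = 0.544), had the smallest p, and was at -0.22 without Ctrl replicate 2. In 89 of the 137 both TUDCA libraries lay below both Ctrl libraries, and in 0 above. Chance separates the groups for a gene 33.3% of the time, both directions counted together. These genes moved together (estimated correlation 0.95), so that rate cannot be set against their count. The camera adjusted p was 5.9e-26, and adjusted p = 0.811 with an estimated correlation. The same genes lay 0.41 higher in Ctrl replicate 2 than in Ctrl replicate 1, a larger gap than that between the groups. Their median was -0.068 without Ctrl replicate 2, -0.47 without Ctrl replicate 1, and -0.18 once a length and GC trend was removed.

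Amino acid synthesis genes, targets of Gcn4, and the histone genes had negative medians that passed camera with the preset correlation but not with an estimated one. Of 29 amino acid genes 28 had fitted values below 0, edgeR and limma called 0 and DESeq2 2, and 8 had an unadjusted p under 0.05. ARG1, of arginine synthesis, had -0.48 (edgeR adjusted p = 0.417), and -0.29 without Ctrl replicate 2, while the glutamate dehydrogenase gene GDH1 had 0.33. The median was -0.17 (camera adjusted p = 1.2e-05, and adjusted p = 0.686 with an estimated correlation). It was -0.077 without Ctrl replicate 2, which lay 0.15 above Ctrl replicate 1. The 9 histone genes had a median of -0.17, with HTA2 at -0.25, and at -0.019 without Ctrl replicate 2 (list camera adjusted p = 0.0264, and adjusted p = 0.860 with an estimated correlation). No histone gene was called by edgeR, DESeq2 or limma, and 0 had an unadjusted p under 0.05. The histone call was lost without TUDCA replicate 1 (camera adjusted p = 0.198) and without Ctrl replicate 2 (0.984), where the median was 0.0041. Without Ctrl replicate 1 that median was -0.29, it was -0.035 once a trend on gene length and GC was removed, and Ctrl replicate 2 lay 0.32 above Ctrl replicate 1.

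Only 4 of the 8 mitochondrially encoded genes listed had enough counts to be tested, and the reason was not tested. The list was written as a sign of poly(A) capture, so capture and expression cannot be told apart in its shift. The mitochondrial 21S ribosomal RNA had a log2 fold change of -0.46 in DESeq2 and did not pass edgeR's test (adjusted p = 0.397). ATP6, a member of the list, had only 13 to 17 counts per library. Mitochondrial features held 0.0112% to 0.0197% of the counts. The ATP synthase gene OLI1 was at 13.3 ± 0.848 CPM in Ctrl and 9.31 ± 0.939 CPM in TUDCA (log2 fold change -0.52, edgeR adjusted p = 0.486), and it was the 1 gene lower when adjusted over the list alone. The tools edgeR, DESeq2 and limma called 0, and 2 had an unadjusted p under 0.05. The median was -0.47 (camera adjusted p = 0.0264, and adjusted p = 0.676 with an estimated correlation). The call was lost without TUDCA replicate 1 (camera adjusted p = 0.198, median -0.29) and on ranks (camera adjusted p = 0.0780). The median was -0.16 without Ctrl replicate 2, which lay 0.23 above Ctrl replicate 1, and -0.096 once a trend on gene length and GC was removed. OLI1 did not pass the adjustment over the list alone without TUDCA replicate 1.

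Genes of hexose transport and its glucose sensing were higher as a list with camera's preset correlation (median 0.15, adjusted p = 5.7e-05), but not with an estimated one (adjusted p = 0.676 with an estimated correlation). Among 15 members edgeR and limma called 0, DESeq2 3, and 6 had an unadjusted p under 0.05. Adjusted over the list alone, 4 rose. These were the transporter genes HXT1 (0.46), HXT2 (0.43) and HXT3 (0.57, from 456 ± 3.48 to 677 ± 80.2 CPM) and MTH1 (0.61), a regulator of hexose transporter expression. The median ranged from 0.021 without Ctrl replicate 2 to 0.39 without Ctrl replicate 1, and was 0.26 without TUDCA replicate 2. Adjusted over the list alone, HXT1, HXT3 and MTH1 passed without TUDCA replicate 1, and HXT2 and MTH1 without TUDCA replicate 2, where HXT1 was at 0.30. Ctrl replicate 2 lay 0.12 below Ctrl replicate 1.

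Genes of respiratory metabolism had small positive medians that passed only with the preset correlation. Of 24 genes of the tricarboxylic acid and glyoxylate cycles and gluconeogenesis, 20 had fitted values above 0, edgeR and limma called 0 and DESeq2 1, and 7 had an unadjusted p under 0.05. The aconitase gene ACO1 had 0.43 (edgeR adjusted p = 0.544). The median was 0.12 (camera adjusted p = 0.000297, and adjusted p = 0.676 with an estimated correlation). It was 0.20 without Ctrl replicate 1, and Ctrl replicate 2 lay 0.085 below that library. The 34 nuclear genes of the respiratory chain and ATP synthase had a median of 0.085 (camera adjusted p = 0.00131, and adjusted p = 0.834 with an estimated correlation). NDI1, the internal NADH dehydrogenase gene, had 0.37, and 0.23 without Ctrl replicate 2. The tools edgeR, DESeq2 and limma called 0 of the 34, and 5 had an unadjusted p under 0.05. The respiratory chain call was lost without Ctrl replicate 1 (camera adjusted p = 0.139) and without TUDCA replicate 1 (0.140, median 0.047). Ctrl replicate 2 lay 0.055 above Ctrl replicate 1 there, and the respiratory chain median was 0.18 once a trend on gene length and GC was removed.

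Osmotic stress genes and the mitotic genes completed the lists that passed camera with the preset correlation, and neither did with an estimated one. GRE2 rose among 14 osmotic stress and ion transport genes, both over all genes and adjusted over the list alone, and edgeR, DESeq2 and limma each called 1. The median was 0.12 (camera adjusted p = 0.00350, and adjusted p = 0.676 with an estimated correlation). The osmotic call was lost without Ctrl replicate 1 (camera adjusted p = 0.0773) and without TUDCA replicate 1 (0.131, median 0.040), and the median was 0.19 without TUDCA replicate 2. Ctrl replicate 2 lay 0.024 above Ctrl replicate 1. Of 12 genes of G2/M and mitotic exit, 10 had fitted values above 0, with HOF1, of cytokinesis, at 0.31 (edgeR adjusted p = 0.544). The tools edgeR, DESeq2 and limma called 0, and 4 had an unadjusted p under 0.05. The median was 0.18 (camera adjusted p = 0.000714, and adjusted p = 0.676 with an estimated correlation), with Ctrl replicate 2 lying 0.14 below Ctrl replicate 1. It was 0.062 once a trend on gene length and GC was removed.

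**Figure D3:**
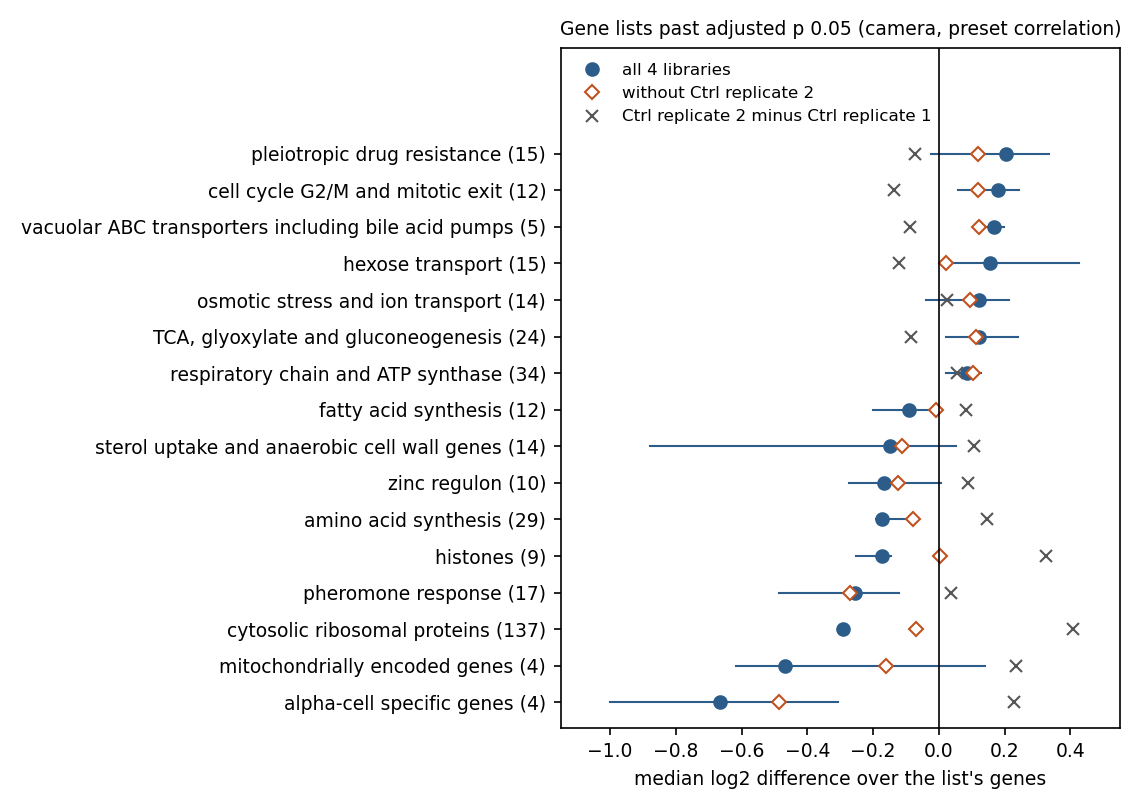
Median log2 differences of the 16 gene lists past an adjusted p of 0.05 in camera with a preset correlation, with measured genes in brackets: blue, TUDCA minus Ctrl with an interval over genes; diamonds, without Ctrl replicate 2; crosses, Ctrl replicate 2 minus Ctrl replicate 1. Ribosomal protein genes lie at -0.29, at -0.068 without Ctrl replicate 2, and at 0.41 between the controls, while pheromone response genes lie at -0.26, -0.27 and 0.036.

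Of the 41 lists tested, 16 passed with the preset correlation, 0 with an estimated correlation, and 25 passed neither way. The test with an estimated correlation has only 2 residual degrees of freedom, so its 0 does not show that correlation made the 16 calls. Nor is correlation excluded for most of them. Among the 16, the estimate lay below the preset 0.01 only for the pheromone and drug resistance lists. For the others it ran from 0.022 (zinc) to 0.97 (α-specific), with 0.96 for histones, 0.52 for fatty acid and 0.30 for respiratory chain genes. Where the estimate lies above the preset, the preset p-values may be too small. The 3 ER lists and the a-specific genes were among the 25, as were the lists of general, heat, oxidative and weak acid stress. General stress genes (Msn2/Msn4) had a median of 0.054 (camera adjusted p = 0.117), with catalase gene CTT1 at 0.31 and HSP12 at -0.14. By counts HSP12 ranked 9 to 11 and HSP26 ranked 13 to 19 across the libraries, so these 2 members were already abundant in Ctrl. Ctrl replicate 2 lay 0.29 below Ctrl replicate 1 for these genes, and the list passed without Ctrl replicate 1 (median 0.23, camera adjusted p = 0.00488) and without TUDCA replicate 2 (median 0.16, 1.3e-05). Its median was -0.045 without Ctrl replicate 2 and -0.040 without TUDCA replicate 1. Heat shock chaperones (Hsf1) had 0.052 (camera adjusted p = 0.569), with HSP60 at 0.20. That list passed in opposite directions without Ctrl replicate 1 (0.20, camera adjusted p = 0.00878) and without Ctrl replicate 2 (-0.079, 0.00311), and passed without TUDCA replicate 2 (0.094, 0.0465), while its median was -0.041 without TUDCA replicate 1. Oxidative stress genes (Yap1) had -0.092 (camera adjusted p = 0.156) and weak acid response genes -0.038 (0.392), with TSA2 at -0.30 and AQR1 at -0.34. With 1 library left out the oxidative median ran from -0.17 (Ctrl replicate 1 out) to -0.047 (Ctrl replicate 2 out). Cell wall integrity targets had 0.041 (camera adjusted p = 0.186), with the MAP kinase gene SLT2 at 0.26 (95% interval 0.079 to 0.45, edgeR adjusted p = 0.544), and the list passed without Ctrl replicate 2 (0.082, camera adjusted p = 0.00884). The cell wall median was -0.026 once a trend on gene length and GC was removed.

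Growth and turnover lists gave values of similar size. Ribosome biogenesis had a median of -0.063 (camera adjusted p = 0.0606), with NSR1 at -0.50, and passed without TUDCA replicate 2 (-0.14, 5.2e-06). Its median was 0.013 without TUDCA replicate 1. Autophagy and vacuolar proteases had 0.14 (camera adjusted p = 0.112), with ATG1 at 0.30, and passed without Ctrl replicate 1 (0.23, 0.00649) and without TUDCA replicate 2 (0.0181). The autophagy median was 0.0065 without Ctrl replicate 2, which lay 0.25 below Ctrl replicate 1, and 0.084 without TUDCA replicate 1. Proteasome genes had 0.0082 (camera adjusted p = 0.787), with RPN1 at 0.19. G1/S genes had 0.060 (camera adjusted p = 0.124), with RAD53 at 0.20, and passed without Ctrl replicate 2 (0.19, 1.4e-07) and without TUDCA replicate 1 (0.16, 0.000701). The G1/S median was -0.060 without Ctrl replicate 1 and -0.050 without TUDCA replicate 2. Daughter cell separation genes had -0.052 (camera adjusted p = 0.932), with DSE4 at 0.25, and meiosis genes -0.027 (0.895), with DIT2 at 0.37. Without Ctrl replicate 2 the daughter separation median was 0.059, and without TUDCA replicate 1 it was 0.042. For daughter separation the median and the mean lay below 0 while camera's direction was up.

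Lipid and carbon lists also did not pass. Ergosterol synthesis had a median of -0.018 (camera adjusted p = 0.586), with ERG2 at -0.23. Sphingolipid synthesis had 0.0060 (camera adjusted p = 0.644), with SUR1 at 0.32, and phospholipid and inositol synthesis 0.045 (0.437), with CHO2 and INO1 each at 0.20. Peroxisomal beta-oxidation had 0.022 (camera adjusted p = 0.450), with PEX5 at 0.14. Glycolysis and fermentation had -0.14 (camera adjusted p = 0.125), with HXK2 at 0.34, and passed without Ctrl replicate 2 (-0.16, 0.000631).

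Nutrient lists were the rest. Nitrogen catabolite repressed genes had a median of -0.011 (camera adjusted p = 0.712), and sulfur assimilation genes -0.00097 (0.790). In both the mean lay above 0, as did camera's direction. The proline permease gene PUT4 had 0.51, and it was the 1 nitrogen gene that rose when adjusted over the list alone. MET16 had -0.27, and JLP1, a sulfonate dioxygenase gene, -0.12 (95% interval -0.41 to 0.18). Purine synthesis had -0.061 (camera adjusted p = 0.404), with IMD4 at -0.21, and passed without Ctrl replicate 1 (-0.17, 0.0233) and without TUDCA replicate 2 (-0.15, 0.00559). The purine median was 0.11 without Ctrl replicate 2 and 0.060 without TUDCA replicate 1. The iron regulon (Aft1) had 0.0090 (camera adjusted p = 0.450), and the metalloreductase gene FRE1, at 0.46, was the 1 member that rose when adjusted over the list alone. The phosphate regulon (Pho4) had 0.013 (camera adjusted p = 0.649), with GDE1 at 0.27. Over the 25 lists edgeR, limma-voom and limma called 0 members, with 0 to 4 members per list at an unadjusted p under 0.05. DESeq2 called PUT4 and FRE1. PUT4 did not pass the adjustment over the list alone without TUDCA replicate 1 or without TUDCA replicate 2, and FRE1 did not without TUDCA replicate 2. Leaving out 1 library changed the sign of the median in 18 of the 25 lists. Library-size scaling moved the median of all genes from -0.0037 to 0.040. This near-uniform shift carried 8 medians close to 0 past it, to 0.019 for ER folding, 0.021 for ER translocation, 0.027 for ergosterol, 0.031 for nitrogen, 0.043 for sulfur, 0.0040 for weak acid, 0.032 for a-specific and 0.017 for meiosis genes.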

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

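Tests with thinned counts, without ribosomal protein genes, with gene length and GC trends, and of list members with each library left out were chosen after seeing the data. The 2 higher and 4 lower genes became 30 and 29 in DESeq2 and 191 and 162 with a replicate block, which pairs libraries that share only a number (correlation of their deviations 0.183). Upper-quartile scaling gave 1 higher, as did an adjusted p under 0.01, and a log2 fold change of at least 1 gave 1 higher and 2 lower, fewer by the construction of the last 2. Leaving out 1 library gave 2 to 1139 higher and 5 to 871 lower. RLE and library-size scaling, limma-voom, limma on the deposited values, a mean count of at least 100, robust dispersion, thinned counts and length and GC offsets each gave 2 and 4. All 6 genes were kept under every alternative fit except upper-quartile scaling and the fit without TUDCA replicate 1, which kept 5. The 16 lists became 0 with an estimated correlation and 0 with fry, and 12 to 20 when 1 library was left out. With the replicate block the vacuolar ABC transporter list no longer passed (camera adjusted p = 0.0556). Ribosome biogenesis (camera adjusted p = 0.0326), general stress (0.0326) and autophagy (0.0426) then passed. HAC1 reversed to 0.014 with library-size scaling and 0.055 without Ctrl replicate 2 (lowest with 1 library left out -0.098). KAR2 reversed to -0.019 with upper-quartile scaling, -0.051 with length and GC offsets and -0.099 without Ctrl replicate 2 (highest 0.17), and YBT1 to -0.0078 with the offsets. The histone median reversed to 0.0041 without Ctrl replicate 2 (lowest -0.29). Of the values for named genes under alternatives, 821 kept direction and side of the threshold, 88 passed it, 2 no longer did and 6 reversed. Of the list medians under alternatives, 261 stayed within the spread between replicates, 66 moved and 1 reversed, where a change of sign counted as a reversal only in the 16 lists that passed. The 33 members past the adjustment over their list alone were 33 without Ctrl replicate 1, 33 without Ctrl replicate 2, 17 without TUDCA replicate 1 and 17 without TUDCA replicate 2. Removing a length and GC trend moved the medians of 9 of the 16 lists by over 1.5 times. Apart from the 2 whose construction shows it, the cause was not tested. In simulated data of this size 83.6% of 1.5-fold changes were called, so part of the changes of that size went uncalled. Smaller ones were not simulated. The simulation changed many more genes than were called here, which eases the Benjamini-Hochberg threshold, so the share called in the data may be lower.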

Other observations

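The tests of a-mating-type cells, of Ctrl replicate 2 alone for the mating and drug resistance genes, the check of overlapping features, and the look at genes called by DESeq2 alone were chosen after the result was seen.

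DESeq2 called genes beyond the 6, of which a few are given here, picked by hand and with no test of a shared function. The external NADH dehydrogenase gene NDE1 had a log2 fold change of 0.62 in DESeq2, HAP4, an activator of respiratory genes, 0.55, and the pyruvate carrier gene MPC3 0.81. The copper transporter gene CTR1 had 0.55 and the cell wall gene TIR1 -1.43. None passed edgeR's test. In edgeR without Ctrl replicate 2 the values were 0.53 for NDE1, 0.42 for HAP4, 0.79 for MPC3, 0.74 for CTR1 and -1.05 for TIR1. Fits with 1 library left out reuse the libraries that gave these calls, so they are not a separate test of them.

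Ctrl replicate 2 differed from Ctrl replicate 1 in ribosomal protein genes (0.41), histones (0.32), heat shock chaperones (-0.30) and general stress genes (-0.29), among other lists. Counting error from unequal depth is argued against, since it was already small beside the spread between libraries. Thinning to the smallest total could therefore change little: the smallest spread with this library stayed 1.59 times the largest spread among the others. A gene length or GC trend is argued against as the whole cause, since the ribosomal protein difference stayed at 0.29 (0.27 to 0.32) once the trend was removed. No biological explanation was tested, and a difference in growth stage between the cultures or in library preparation may underlie it.

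Mating genes of the α strain were lower in TUDCA, with a median of -0.31 over 21 pheromone and α-specific genes, of which 3 passed edgeR's test, though neither list passed camera with an estimated correlation (adjusted p = 0.462 and 0.530) or fry (0.137 and 0.363). The estimate was -0.025 for the pheromone list, below the preset 0.01, and 0.97 for the α-specific list. That camera test has only 2 residual degrees of freedom. The median was -0.27 (interval over genes -0.53 to -0.14) without Ctrl replicate 2, and -0.33 (-0.68 to -0.21) after a length or GC trend was removed. These values argue against either as the whole cause. The intervals treat co-regulated genes as independent. With only 1 Ctrl library left in the first case, variation between libraries is not excluded. Cells of mating type a in the controls cannot be told apart from the lower mating genes: the a-specific median was -0.012, but the low end of its interval (-0.30 to 0.20) is the value of MFA2, which lay below Ctrl in both TUDCA libraries. MFA2 (95% interval -0.74 to 0.14) and MFA1 (-0.63 to 0.34), the transcripts such cells would raise first, do not exclude a fall of that size. A lower basal mating signal under TUDCA may be the source, a hypothesis that was not tested.

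PDR5 was higher in TUDCA, and the drug resistance list was with camera's preset correlation but not with an estimated one (adjusted p = 0.499) or fry (0.155), with 14 of its 15 members not past edgeR's test. The correlation estimated for that list, -0.0014, lay below the preset 0.01. For PDR5, the log2 fold change was 1.19 (0.97 to 1.40) without Ctrl replicate 2 and 1.06 (0.85 to 1.3) with length and GC offsets, and its gain was 4.54 times the control level of its paralog PDR15, which argues against all 3 explanations. For the list, the median was 0.12 (-0.024 to 0.31) without Ctrl replicate 2 and 0.072 (-0.051 to 0.29) after a length and GC trend was removed. These 2 tests could not decide for the list, which cannot be told apart from either. The reason is that its interval before (-0.023 to 0.34) already included 0. Activation of drug efflux by the bile acid may explain PDR5, a hypothesis that was not tested.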
